A study of Mus musculus with 8 samples.

How the data were processed

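The series holds 8 libraries of mouse heart RNA, 4 from db/db mice given vehicle and 4 from db/db mice given DIZE, grouped by the treatment in the labels. Per the labels' protocols, RNA was extracted with TRIzol, and libraries were made from poly(A)-selected RNA with a stranded mRNA kit and sequenced as read pairs on a NovaSeq instrument. The submitters' processing notes name STAR 2.7.3, HTSeq 0.6.1p1, edgeR and R 4.1 and the genome build mm10, without saying which settings were used. The annotation release and whether HTSeq counted by strand are not given in the sources used here.

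The deposited table holds raw counts, whole numbers of reads per Ensembl gene, for 55487 genes in 8 columns, and no value had been normalized. Each column was tied to its sample by the sample's own description in the labels, and there were 0 columns from other samples. Gene symbols were matched by Ensembl ID for 55141 genes, and 346 had no match. Positions, overlaps, transcript length and GC content came from the GENCODE annotation of GRCm38, the same assembly as mm10.

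Total counts ranged from 7447664 to 10161623. At this depth a level of 1 CPM stands for few reads, so low genes carry large counting error. CPM values, log2 fold changes and their standard errors were computed here from the deposited counts, and values with SD are over the 4 libraries of a group. CPM are counts scaled to the library's reads in tested genes times its TMM factor. The means given for overlapping genes were scaled to the library total instead. Before averaging, every pair of libraries was compared by a chi-square statistic over genes. The most alike pair still gave 5.57 per degree of freedom, so no 2 libraries agreed within sampling noise.

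The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust, two-sided) with TMM factors and no covariate. Genes were kept by filterByExpr (minimum count 10, minimum total 15), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists with at least 3 tested members. There were 38 lists, of pathways and of markers of cell types and neighbouring tissues, of which 36 were tested. The lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined.

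Genes are named by this rule. In each direction, up to 12 genes with the largest change are named among those past the threshold, with a mean of at least 1 CPM and no overlap between the groups. Where fewer than 5 qualify, the genes with the smallest unadjusted p under the same conditions fill the number up to 5 and are given as values. Up to 4 members per list with the smallest unadjusted p may be named, and 15 genes of the study's subject are always named, of which 1 is not reported here. Placeholder symbols are counted and not named. Any other gene is stated to have been chosen after its values were seen.

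The alternatives were DESeq2 1.42.0, the edgeR exact test, limma-voom with and without library weights, other size factors, other filters, 1 surrogate variable (sva 3.50.0), the form of the sample titles as a block, the number in the titles as a block, and leaving out each library in turn with the same filter applied again. Title form was assigned here by whether a title holds the letters db, in either case. Added after the data were examined were a correction for GC content and transcript length, the level of Myl7 as a covariate, the 2 title forms taken alone, the test without its robust option, fry with each library left out and a threshold of 0.1.

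The procedure was tested on simulated data, in 10 simulations of the DIZE and vehicle comparison with 13648 genes and 200 changed genes each. The test recovered 19.3% of genes changed 1.5-fold, 68.1% of those changed 2-fold and 95.5% of those changed 4-fold, and 6.39% of the calls were false. A shifted list was called in all 10 simulations, and 0.3 other lists per simulation. The simulated libraries had independent genes, which real libraries do not.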

Results

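The data were gene-level read counts from the hearts of db/db mice, which carry a mutated leptin receptor and develop obesity and type 2 diabetes. One group of 4 libraries came from mice given vehicle. The other group of 4 came from mice given DIZE, taken here as diminazene aceturate, an antiprotozoal drug. Total counts were 8770388, 8149211, 7447664 and 10056759 in vehicle 1 to 4, and 8461767, 8042396, 10113372 and 10161623 in DIZE 1 to 4. Of 55487 annotated genes, 13648 had enough reads to be tested. The labels do not state whether each library came from a separate animal, so p-values measure the spread between these samples.

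The comparison of DIZE with vehicle addresses the series' stated subject, which is whether the treatment acts on diabetic cardiomyopathy through oxidative stress. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5 genes changed, 3 upward and 2 downward, and for each of them all 4 DIZE libraries lay beyond all 4 vehicle libraries. CPM are counts scaled to the library's reads in tested genes times its TMM factor, given as mean ± SD with n = 4 per group. Tmem171, which encodes a transmembrane protein, rose 3.63-fold, from 3.56 ± 1.22 to 12.8 ± 1.88 CPM (log2 fold change 1.86 ± 0.23 SE, edgeR adjusted p = 0.0376). Pim1, a serine/threonine kinase gene, rose 2.11-fold, from 10.8 ± 0.73 to 22.9 ± 1.95 CPM (log2 1.08 ± 0.12, adjusted p = 0.0345). Plcd3, a phospholipase C gene, rose 2.03-fold, from 17.2 ± 2.81 to 34.9 ± 2.89 CPM (log2 1.02 ± 0.14, adjusted p = 0.0423). With each library's trend on GC content and transcript length removed, a correction chosen after the data were examined, Plcd3 had log2 0.69 ± 0.15 and did not pass (edgeR adjusted p = 0.0744). Gpc6, which encodes a glypican of the cell surface, was 3.14-fold lower, with 13.9 ± 4.45 CPM in vehicle and 4.38 ± 0.52 CPM in DIZE (log2 -1.65 ± 0.23, adjusted p = 0.0445). Tcim was 1.99-fold lower, with 88.7 ± 15.0 CPM in vehicle and 44.6 ± 3.10 CPM in DIZE (log2 -0.99 ± 0.13, adjusted p = 0.0423).

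The identifiers and positions of these genes, on the mouse assembly GRCm38 (mm10), were as follows. Tmem171 (ENSMUSG00000052485) lies on chromosome 13 from 98686235 to 98694834. Pim1 (ENSMUSG00000024014) lies on chromosome 17 from 29490753 to 29496112. Plcd3 (ENSMUSG00000020937) lies on chromosome 11 from 103070304 to 103101658. Gpc6 (ENSMUSG00000058571) lies on chromosome 14 from 116925315 to 117976544. Tcim (ENSMUSG00000056313) lies on chromosome 8 from 24437180 to 24438984. Pim1, Gpc6 and Tcim each overlap an annotated gene on the other strand, with a mean below 1 CPM in each case.

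The next genes in order of unadjusted p, with groups that did not overlap, missed the adjusted threshold and are given as values. Cnksr3, a scaffold protein gene, had 31.8 ± 5.88 CPM in vehicle and 61.5 ± 3.8 CPM in DIZE (edgeR adjusted p = 0.0569). Kif23, a kinesin of cell division, had 3.37 ± 0.12 and 0.82 ± 0.42 CPM (adjusted p = 0.0707). Slc24a2, a sodium/calcium exchanger gene, had 6.45 ± 1.87 and 2.15 ± 0.26 CPM, and the clock genes Arntl and Per3 are described below with their list (adjusted p = 0.0707 each). Over all genes tested, 1696 (12.4%) had no overlap between the groups, where chance gives 2.86%. At an unadjusted p under 0.05 there were 2647 genes, 1243 higher and 1404 lower in DIZE, against 682 expected by chance. Other equal splits of the libraries gave a median of 494 such genes and at most 1814.

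**Figure D1:**
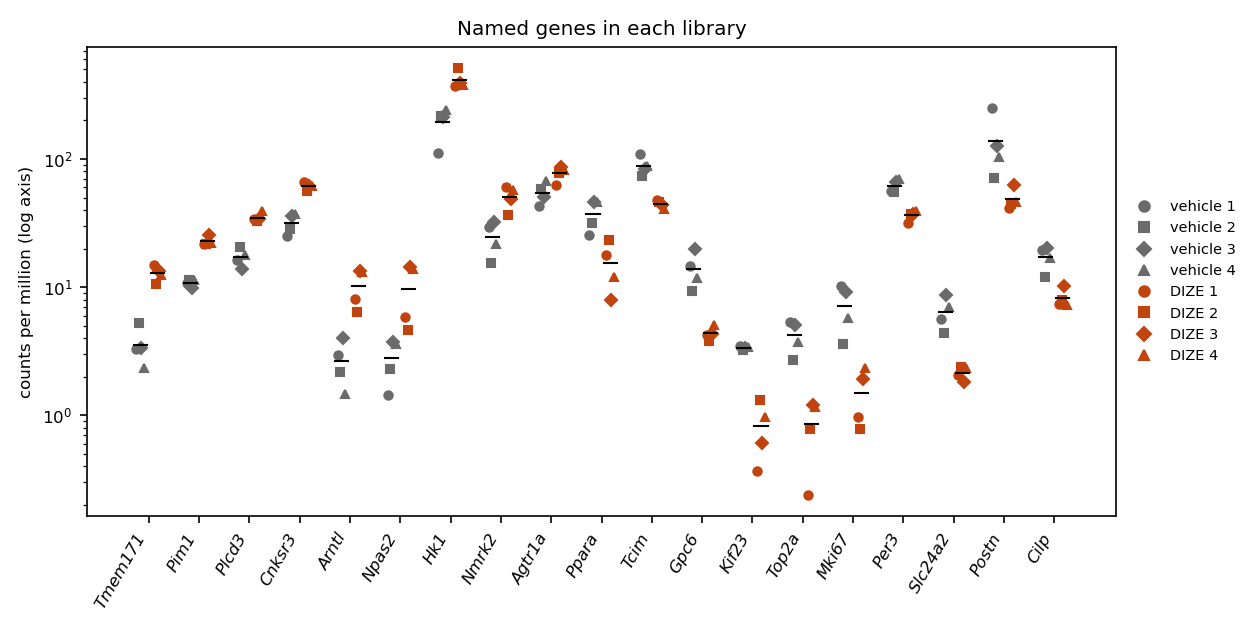
CPM (log axis) of 19 named genes in each of the 8 libraries, vehicle in grey and DIZE in red, with a symbol per replicate and a black line at each group mean. Tmem171, Pim1, Plcd3, Tcim and Gpc6 passed the adjusted threshold, while Agtr1a overlapped between the groups, at 42.8 to 67.7 CPM in vehicle and 62.8 to 86.8 CPM in DIZE.

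Transcripts of the renin-angiotensin system did not pass as a group. Of 13 tested members of that list, none passed over all genes or when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.98, median log2 fold change 0.07, or -0.07 without vehicle 1, mean -0.01). Ace, which encodes the enzyme that forms angiotensin II, had 78.2 ± 12.2 CPM in vehicle and 67.2 ± 2.78 CPM in DIZE (log2 -0.22 ± 0.13, and -0.13 without vehicle 3). Mas1, the receptor gene for angiotensin-(1-7), had 2.30 ± 1.05 and 2.57 ± 1.80 CPM (log2 0.22 ± 0.52). Mas1 overlaps Airn, a more abundant transcript on the other strand, so its reads are uncertain, and its sign turned without vehicle 1 (log2 -0.07) or DIZE 3 (-0.19). Agtr1a, the angiotensin II receptor gene, had 54.7 ± 10.7 and 77.4 ± 10.5 CPM (log2 0.50 ± 0.16, edgeR adjusted p = 0.142).

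The antioxidant list did not pass either. Of its 35 tested members, 20 lay higher and 15 lower, none passed over all genes or adjusted over the list alone, and the median log2 fold change was 0.03 (camera adjusted p = 0.732). Sod2, the mitochondrial superoxide dismutase, had 678.5 ± 74.0 CPM in vehicle and 755 ± 55.2 CPM in DIZE (log2 0.15 ± 0.11, and 0.24 without vehicle 2). Cat, the catalase gene, had 554 ± 130.1 and 614 ± 78.3 CPM (log2 0.15 ± 0.17). Cat was at 394 CPM in vehicle 1, and its log2 value was 0.01 without that library, 0.29 without vehicle 2 and 0.08 without DIZE 1. Keap1, which encodes a repressor of the antioxidant regulator NRF2, had log2 0.29 ± 0.12, and Gpx1, a glutathione peroxidase gene, had log2 -0.40 ± 0.17. Among 16 tested enzymes that produce reactive oxygen species, none passed in either way (camera adjusted p = 0.732). Nox4, an NADPH oxidase gene, had 4.37 ± 2.87 CPM in vehicle and 2.42 ± 0.74 CPM in DIZE (log2 -0.85 ± 0.41, edgeR adjusted p = 0.288). Its vehicle mean rested on vehicle 1, at 8.62 CPM against 2.28 to 3.33 CPM in the other 3, and Nox4 had log2 -0.28 without it. Cybb, the catalytic subunit of the phagocyte oxidase, had 23.8 ± 9.95 and 17.7 ± 3.00 CPM (log2 -0.43 ± 0.26). Vehicle 1 was at 37.2 CPM of Cybb against 13.2 to 22.5 CPM in the other vehicle libraries, and without it log2 was -0.13. The lipoxygenase gene Alox12 had log2 0.99 ± 0.27 (adjusted p = 0.121).

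Of the 36 gene lists with at least 3 tested members, 8 passed camera with its preset correlation, 3 toward higher and 5 toward lower values in DIZE. None of the 8 passed with an estimated correlation, and none passed fry's directional test. Of the 35 ways to split the 8 libraries into 2 sets of 4, 28 gave 8 or more lists.

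**Figure D2:**
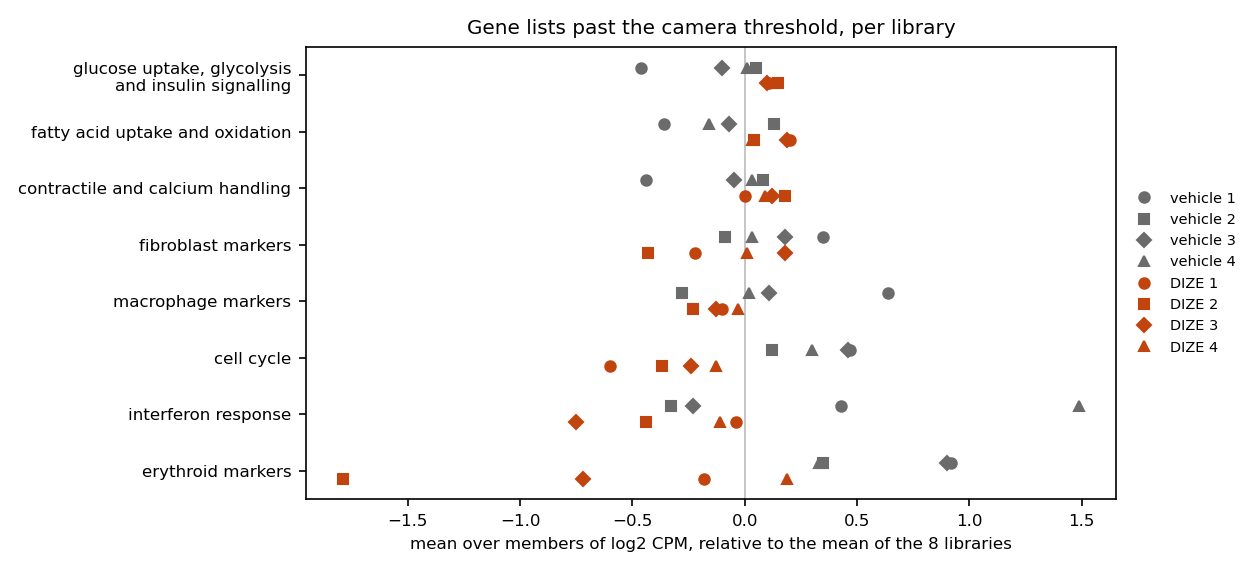
Mean over the members of each gene list of log2 CPM, relative to the mean of the 8 libraries, for the 8 lists past the camera threshold, vehicle in grey and DIZE in red, with a symbol per replicate. The cell cycle list separated the groups, at 0.12 to 0.47 in vehicle and -0.60 to -0.13 in DIZE, while vehicle 4 stood at 1.49 for the interferon list and vehicle 1 at -0.46 for the glucose list.

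Genes of cell division passed as a list toward lower values in DIZE. Of 20 tested cell cycle genes, 17 lay lower and 3 higher, with a median log2 fold change of -0.42 (camera adjusted p = 1.56e-07; adjusted p = 0.67 with an estimated correlation; fry adjusted p = 0.0602). None passed over all genes, and 8 passed, all lower, when adjusted over the list alone. These levels were low. Mki67, a marker of proliferating cells, had 7.20 ± 3.05 CPM in vehicle and 1.51 ± 0.74 CPM in DIZE (log2 -2.21 ± 0.40, edgeR adjusted p = 0.0707). Top2a, a DNA topoisomerase gene, had 4.21 ± 1.24 and 0.85 ± 0.45 CPM (log2 -2.25 ± 0.39). Cdk1, the mitotic kinase gene, had 2.09 ± 0.61 and 0.44 ± 0.36 CPM, and Kif11, a spindle motor gene, had 3.32 ± 0.41 and 1.45 ± 0.34 CPM. All 4 DIZE libraries lay below all 4 vehicle libraries for each of these genes.

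Matrix genes went both ways. For the matrix list, fry's test for change in either direction gave adjusted p = 0.0151. It gave 0.0922 without vehicle 4, 0.0822 without DIZE 2 and 0.0642 without DIZE 4. Of 42 tested genes of extracellular matrix and fibrosis, 26 lay lower and 16 higher (median log2 -0.19, camera adjusted p = 0.0858, and 0.00205 toward lower with the GC and length trend removed), none passed over all genes, and 5 lower and 1 higher passed adjusted over the list alone. Postn, the periostin gene, had 137.6 ± 77.8 CPM in vehicle and 48.8 ± 9.78 CPM in DIZE (log2 -1.49 ± 0.34, edgeR adjusted p = 0.0919). Postn was at 249 CPM in vehicle 1 against 70.9 to 125.6 CPM in the other vehicle libraries. Left-out libraries moved its log2 value between -1.71 and -1.04. Thbs4, a thrombospondin gene, had 24.3 ± 9.09 and 11.1 ± 1.32 CPM (log2 -1.14 ± 0.24). Cilp had 17.1 ± 3.75 and 8.19 ± 1.37 CPM (log2 -1.06 ± 0.19), and Ltbp2, a latent TGF-beta binding protein gene, had log2 -1.02 ± 0.20. The collagen genes differed in sign, with log2 0.34 ± 0.29 for Col1a1 and -0.42 ± 0.29 for Col3a1. These values moved with single libraries, to 0.09 for Col1a1 without vehicle 1, at 45.2 CPM against 101.6 to 133.4 CPM in the other vehicle libraries, and to -0.21 for Col3a1 without vehicle 3. Without DIZE 3 Col1a1 had 0.19, and without DIZE 1 Col3a1 had -0.26. Tgfb1 had log2 0.18 ± 0.17, and 0.02 without vehicle 1, at 18.5 CPM against 30.4 to 33.1 CPM in the other vehicle libraries. Fibroblast markers passed as a list, with 12 of 15 lower (median log2 -0.21, or -0.08 without vehicle 1, camera adjusted p = 0.0491; adjusted p = 0.845 with an estimated correlation). Of these, 3 passed, all lower, when adjusted over the list alone, namely Ddr2 (log2 -0.81 ± 0.18), Pi16 (-0.62 ± 0.16) and Mfap5 (-0.63 ± 0.18). The fibroblast call was lost without vehicle 1 (adjusted p = 0.175), vehicle 3 (0.0612), DIZE 1 (0.133) or DIZE 2 (0.451), and with the level of the atrial marker Myl7 as a covariate (0.279).

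Lists of fatty acid and glucose genes passed toward higher values in DIZE, by small amounts. Vehicle 1 stood apart on both, at -0.36 and -0.46 relative to the mean of the 8 libraries, and without it the medians were 0.16 for fatty acid and 0.14 for glucose genes. Of 44 genes of fatty acid uptake and oxidation, 38 lay higher and 6 lower (median log2 0.20, camera adjusted p = 2.08e-05; adjusted p = 0.845 with an estimated correlation). None passed over all genes or adjusted over the list alone. Acadvl, the very-long-chain acyl-CoA dehydrogenase gene, had 562 ± 67.2 CPM in vehicle and 741 ± 53.5 CPM in DIZE (log2 0.40 ± 0.12, edgeR adjusted p = 0.128). Mlycd, which encodes malonyl-CoA decarboxylase, had log2 0.54 ± 0.16, and Ucp2 had log2 0.71 ± 0.21. Ppara, a nuclear receptor gene that promotes transcription of this pathway, lay in the other direction, with 37.4 ± 10.6 CPM in vehicle and 15.4 ± 6.80 CPM in DIZE (log2 -1.29 ± 0.31, adjusted p = 0.0993). Of 33 genes of glucose uptake, glycolysis and insulin signalling, 27 lay higher (median log2 0.21, camera adjusted p = 0.000247; adjusted p = 0.845 with an estimated correlation). Hk1, a hexokinase gene, was the 1 member past the threshold adjusted over the list alone, with 195.2 ± 57.4 CPM in vehicle and 413 ± 65.2 CPM in DIZE (log2 1.08 ± 0.21, edgeR adjusted p = 0.0815). Gpi1 had log2 0.48 ± 0.14, Gys1, the muscle glycogen synthase gene, which overlaps a gene on the other strand, 0.76 ± 0.25, and Akt2, a kinase gene of insulin signalling, 0.30 ± 0.10. Nuclear genes of oxidative phosphorylation did not pass, with 29 of 62 higher (camera adjusted p = 0.93 toward higher, median log2 -0.04, or 0.01 without vehicle 1, mean -0.01). With the GC and length trend removed, they passed toward higher values (camera adjusted p = 0.00847, median 0.10). The 13 mitochondrially encoded genes all lay lower (camera adjusted p = 0.0925), and turned to higher with that correction (0.0208, median 0.19).

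Of 32 genes of contraction and calcium handling, 27 lay higher (median log2 0.18, camera adjusted p = 0.00756; adjusted p = 0.845 with an estimated correlation), and none passed over all genes or adjusted over the list alone. Actn2, which encodes alpha-actinin of the Z-disc, had 1775 ± 616 CPM in vehicle and 2712 ± 276 CPM in DIZE (log2 0.61 ± 0.23). Myom2 had log2 0.53 ± 0.18, Tnnt2, the cardiac troponin T gene, 0.28 ± 0.11, and Myh6, the alpha myosin heavy chain gene, 0.29 ± 0.20. Vehicle 1 stood apart here, with 8858 CPM of Myh6 against 15569 to 19354 CPM in the other 3 vehicle libraries. Without it Actn2 had log2 0.40 and Myh6 0.10, the median was 0.09 and the list did not pass (camera adjusted p = 0.175). The GC content of a gene also moved with the groups. Across 11477 genes, which are not independent replicates, Spearman's rho between log2 fold change and GC content was 0.42, with a median of -0.14 in genes under 43.8% GC and 0.21 in genes over 55.4% GC. The trend was steepest in vehicle 1 (rho = -0.50).

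**Figure D3:**
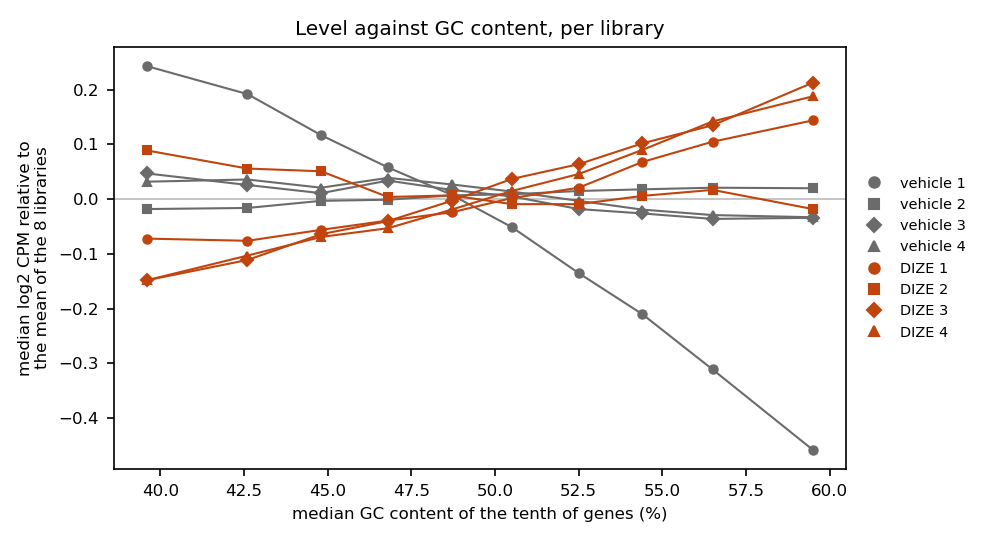
Median log2 CPM relative to the mean of the 8 libraries, against the median GC content (%) of each of 10 sets of 11477 genes ordered by GC, with 1 line per library (vehicle grey, DIZE red). Vehicle 1 went from 0.243 in the set lowest in GC to -0.458 in the highest, and DIZE 3 from -0.148 to 0.213.

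Genes linked to hypertrophy and cardiac stress moved in both directions. Of 19 members, 4 higher and 3 lower passed adjusted over the list alone, and fry's test for change in either direction gave adjusted p = 0.000409, while camera gave adjusted p = 0.732. The median was -0.07 and the mean 0.02. Mybpc2 had 30.8 ± 5.06 CPM in vehicle and 16.9 ± 2.43 CPM in DIZE (log2 -0.86 ± 0.15, edgeR adjusted p = 0.0707), and Xirp2, which encodes an intercalated disc protein, had 614 ± 97.6 and 387 ± 17.3 CPM (log2 -0.67 ± 0.12). Rcan1, an inhibitor of calcineurin, had 88.4 ± 9.25 and 127.3 ± 3.21 CPM (log2 0.53 ± 0.11). Nmrk2, a nicotinamide riboside kinase gene, had 24.7 ± 7.51 and 51.0 ± 10.7 CPM (log2 1.05 ± 0.23). Nmrk2 overlaps an annotated antisense gene, Atcayos, with a mean of 78.6 CPM, so its reads are uncertain where the counting ignored strand. The natriuretic peptide genes did not pass, with log2 -1.04 ± 0.39 for Nppa (adjusted p = 0.199) and -0.07 ± 0.38 for Nppb, nor did Myh7, the beta myosin heavy chain gene, which also overlaps antisense genes (log2 -0.28 ± 0.30). Nppa was at 84.5 CPM in vehicle 1 against 26.9 to 43.1 CPM in the other vehicle libraries, and had log2 -0.58 without it. Left-out libraries moved Myh7 between -0.50 and -0.08 and Nppb between -0.54 and 0.19. Nppa is also an atrial transcript. The atrial markers Myl7 and Sln, of which Myl7 was chosen after its values were seen, varied within both groups, Myl7 from 0.67 to 279 CPM in vehicle and from 0.79 to 42.1 CPM in DIZE.

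Interferon response genes, macrophage markers and erythroid markers passed as lists toward lower values in DIZE, and other immune lists did not pass. All 29 tested interferon response genes lay lower (median log2 -0.83, camera adjusted p = 1.27e-07; adjusted p = 0.845 with an estimated correlation), none passed over all genes, and 4 passed adjusted over the list alone. These were Isg15 (log2 -1.20 ± 0.26), Ifi44 (-1.79 ± 0.50), Trim30a (-0.78 ± 0.23) and Parp14 (-1.22 ± 0.36). Vehicle 4 stood apart, with 535 CPM of the interferon-induced GTPase gene Igtp, chosen after its values were seen, against 13.5 to 30.1 CPM in the other vehicle libraries. Igtp overlaps Irgm2 on the same strand, so their reads are uncertain. Without vehicle 4 the median of the list was -0.38 (camera adjusted p = 0.00632), with -1.18 for Ifi44 and -0.72 for Parp14. Of 20 macrophage markers, 17 lay lower (median log2 -0.34, camera adjusted p = 0.0368; adjusted p = 0.845 with an estimated correlation), with log2 -0.47 ± 0.17 for C1qb, -0.40 ± 0.17 for C1qa and -0.78 ± 0.31 for Folr2, which overlaps a transcript of similar level on the other strand. None passed over all genes or adjusted over the list alone. Without vehicle 1 the macrophage median was -0.06 (camera adjusted p = 0.464), with -0.27 for C1qb and -0.21 for C1qa, and the list also failed without DIZE 2 (0.105) and with the level of Myl7 as a covariate (0.254). Of 22 genes of inflammatory cytokines and adhesion, 14 lay lower and 8 higher (camera adjusted p = 0.264). The 6 mast cell markers (0.0858) and the 3 markers of B and plasma cells (0.194) all lay lower without passing, and 2 of 3 neutrophil markers lay higher (0.462). Of 8 erythroid markers, 7 lay lower (median log2 -1.47, camera adjusted p = 0.00146; adjusted p = 0.845 with an estimated correlation), none passed over all genes, and 5 passed adjusted over the list alone. The globin gene Hba-a1 had log2 -1.72 ± 0.52, and Hbb-bt had log2 -2.02 ± 0.48. Globin genes share reads with near-identical copies, so the split between copies is uncertain.

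Circadian clock genes differed in both directions. Of 20 members, 2 higher and 4 lower passed adjusted over the list alone, none passed over all genes, and fry's test for change in either direction gave adjusted p = 0.000792 (camera adjusted p = 0.93, median log2 -0.03, or 0.06 without vehicle 4, mean 0.15). Arntl (Bmal1), the activator of the core loop, had 2.66 ± 1.09 CPM in vehicle and 10.2 ± 3.53 CPM in DIZE (log2 1.97 ± 0.33, edgeR adjusted p = 0.0707). Npas2, a partner of Arntl, had 2.78 ± 1.11 and 9.69 ± 5.17 CPM (log2 1.82 ± 0.42). Per3 had 61.8 ± 7.16 and 36.3 ± 3.24 CPM (log2 -0.77 ± 0.12, adjusted p = 0.0707), and Nr1d2, a repressor of the same loop, had 199 ± 42.2 and 122.9 ± 18.5 CPM (log2 -0.70 ± 0.17). Per3 overlaps Camta1 on the same strand, so its reads are uncertain. Within DIZE, some clock genes, among them Arntl, Npas2, Dbp and Nr1d1, differed by the form of the sample titles. Arntl was at 8.06 and 6.45 CPM in DIZE 1 and 2, which share a form, and at 13.4 and 13.1 CPM in DIZE 3 and 4, and Npas2 was at 5.86 and 4.61 against 14.3 and 13.9 CPM. Dbp, chosen after its values were seen, was at 15.7 and 25.1 against 69.9 and 74.3 CPM. Nr1d1, also chosen after its values were seen, was at 64 and 80.9 against 239 and 195 CPM. Dbp also differed by form within vehicle, at 51.1 and 49.1 against 83.4 and 72.7 CPM. So did Nr1d1, at 37 and 56.4 against 152 and 78.4 CPM. Within DIZE, Nr1d2 did not separate by form (104.75 and 146.44 against 112.17 and 128.32 CPM). Per3 differed little (31.74 and 36.97 against 37.09 and 39.39 CPM). The labels used here give no time of collection.

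The count of 5 genes depended on single libraries. Without 1 library it ranged from 0 to 240. It was 9 without vehicle 1, 240 without vehicle 2, 1 without vehicle 3, and 0 by edgeR without vehicle 4 (2514 at an unadjusted p under 0.05) or without any 1 of the 4 DIZE libraries (1965 to 2534). Over these leave-outs log2 ranged from 1.02 to 1.11 for Pim1, 1.70 to 2.10 for Tmem171 and 0.93 to 1.11 for Plcd3. For Tcim it ranged from -1.07 to -0.88, and for Gpc6 from -1.79 to -1.44. DESeq2, run without the low-count filter (28260 genes), called 588 genes with all 8 libraries, where edgeR without that filter called 386. The sample titles were sorted here into 2 forms, those with the letters db and those without, each covering 2 libraries of each group. The labels do not say what this difference means. Within 1 form the edgeR test called 0 genes (1132 at an unadjusted p under 0.05) and within the other 1349, against 5 over both.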

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

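The tests of Igtp, Gbp2, Myl7 and Tef were chosen after the result was seen. The values tested for a sample far from the rest of its group were the CPM of the named genes, the levels of the 8 lists past the camera threshold and the total counts, in 172 groups of 4. Chance gives about 1 in 20 such groups, or 8.6 here, and 13 were found. No explanation was tested for them.

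Vehicle 2 stood apart in liver transcripts, with Alb at 1350 CPM against 0 to 6.38 CPM in the other vehicle libraries, and Hp at 144 CPM against 0.939 to 8.41 CPM. Its Sod2 level was 789 CPM, against 629 to 653 CPM in the other vehicle libraries. Vehicle 4 stood apart in interferon-induced GTPase genes, with Igtp at 535 CPM against 13.5 to 30.1 CPM, and Gbp2 at 210 CPM against 16.0 to 39.2 CPM. Igtp and Gbp2 were chosen after their values were seen. Vehicle 1 stood apart with Nox4 at 8.62 CPM against 2.28 to 3.33 CPM, Folr2 at 4.41 CPM against 2.44 to 2.68 CPM, and Mmp9 at 0.616 CPM against 1.28 to 1.41 CPM.

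Among the DIZE libraries, DIZE 2 had Nppb at 138 CPM against 50.8 to 57.4 CPM in the other 3, Nox4 at 1.32 CPM against 2.73 to 2.83 CPM, and Hk1 at 510 CPM against 371 to 390 CPM. Cybb was at 22.1 CPM in DIZE 4 against 15.7 to 16.8 CPM, and C1qb at 72.2 CPM in DIZE 1 against 60.2 to 61.2 CPM.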

How the results depend on the processing

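The GC and length correction, the Myl7 covariate, the separate title forms, the test without its robust option and the threshold of 0.1 were chosen after the data were examined. The count of 5 genes was 5 with DESeq2 size factors, 6 with upper-quartile factors, and 4 with a filter at a mean of 1 CPM, with limma-voom or without the robust option, each without Gpc6. It was 386 without a low-count filter and 588 with DESeq2, which was also run without that filter. The edgeR exact test gave 477 and library quality weights 446. The count was 245 at an unadjusted p under 0.05 with at least a 2-fold change, and 219 at adjusted p under 0.1 (81 higher, 138 lower). It was 9 with the title form as a block and 10 with the GC and length trend removed, where Plcd3 was lost (log2 0.69 ± 0.15, adjusted p = 0.0744), its shift being smaller at a like error. The edgeR count was 0 with a surrogate variable (2469 at an unadjusted p under 0.05), 0 with the Myl7 covariate (2092), and 0 within 1 title form (1132) against 1349 within the other. Leaving out 1 library gave 0 to 240. The edgeR counts of 0 had 2514 genes at an unadjusted p under 0.05 without vehicle 4 and 1965 to 2534 without a DIZE library. The smallest adjusted p was 0.0684 without vehicle 4 and 0.0674 to 0.181 without a DIZE library. The cause of these differences was not tested. Pim1, Tmem171, Plcd3 and Tcim each passed in 2 of the 8 leave-outs and Gpc6 in 1, and their direction held in all 24 settings that gave a value.

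The numbers in the titles occur more than once within a group, so they give no unique pairing of all samples. Among titles with the letters db each number occurs once in each group, and the labels state no pairing. Libraries with the same number deviated from their group means with correlations of -0.14 to 0.02. With the number as a replicate block over 6 libraries, edgeR called 0 genes (smallest adjusted p 0.162, 1943 at an unadjusted p under 0.05) and camera 12 lists. This fit leaves out vehicle 4 and DIZE 3, and the interferon call was lost in it (camera adjusted p = 0.248).

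The count of 8 lists was 0 with an estimated correlation and 0 with fry, 14 within 1 title form and 6 within the other, 12 with the GC and length trend removed (all 8, with matrix, endothelial, oxidative phosphorylation and mitochondrially encoded genes), and 7 to 11 without 1 library. The cell cycle, fatty acid, glucose, interferon and erythroid lists passed in all 8 leave-outs. Within the title form that called 1349 genes, fibroblast markers turned to higher in DIZE (adjusted p = 0.952), and the erythroid (0.283), macrophage (0.283) and contractile (0.06) calls were lost. With the Myl7 covariate the fibroblast (0.279) and macrophage (0.254) calls were lost. None of the following genes passed the threshold, and their signs turned. Within 1 title form log2 was -0.71 for Mas1, 0.59 for Nppb, 0.71 for Igtp and 0.08 for Gbp2, and within the other it was -0.04 for Tgfb1, 0.02 for Gpx1 and 0.47 for Hp. With the replicate block it was -0.12 for Mas1, 1.09 for Igtp and 0.33 for Gbp2, and with the GC correction 0.19 for Nppb. Without 1 library, Mas1 ranged from -0.19 to 0.50, Nppb from -0.54 to 0.19, Igtp from -2.38 to 0.81 and Gbp2 from -1.80 to 0.04. The median log2 fold change of all genes moved by 0.003 with DESeq2 size factors and by -0.013 with upper-quartile factors. Depth limits genes near 1 CPM, such as Mas1 and Cdk1.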

Other observations

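The tests with the GC and length correction, without vehicle replicate 1, by time of day, with the Myl7 covariate and of fry with each library left out were chosen after the data were examined, and those of vehicle replicate 1, of time of day and of each gene-by-gene change only after the result was seen. Adipocyte and immediate early genes were among the lists not yet described. Of 9 white adipocyte markers, 1 higher and 2 lower passed adjusted over the list alone, and fry's test for change in either direction gave adjusted p = 0.00331 while camera gave 0.415. Vehicle 2 stood apart on this list, at 0.67 against -0.28 to 0.03 in the other libraries, and without it fry gave 0.0122 (0.00244 to 0.0494 over the 8 leave-outs). Lipe, the hormone-sensitive lipase gene, had 64.2 ± 6.90 CPM in vehicle and 96.5 ± 15.0 CPM in DIZE (log2 0.59 ± 0.14, edgeR adjusted p = 0.0919). Thrsp, a lipogenic regulator gene, had 37.1 ± 11.1 and 21.5 ± 3.04 CPM (log2 -0.79 ± 0.20), with 52.97 CPM in vehicle 2 and log2 -0.56 without that library. Myc was the 1 of 24 immediate early genes past the threshold adjusted over the list alone (log2 0.97 ± 0.23). The matrix protease gene Mmp9 had 1.16 ± 0.37 CPM in vehicle and 2.91 ± 0.70 CPM in DIZE (log2 1.34 ± 0.31), the cytokine gene Il33 had log2 -0.91 ± 0.30 (-0.58 without vehicle 1), and Uqcrc1, of respiratory complex III, had log2 0.39 ± 0.14. None of these genes passed over all genes tested.

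For the count of genes, the real split ranked highest, at the smallest two-sided exact permutation p this design can give (0.0286). This makes chance unlikely without excluding it, and for the count of lists chance remains open. The real split gave 5 genes, the highest of the other 34 splits gave 1, and 1 of the 35 splits, the real one, gave as many. For the lists, the real split gave 8, the highest other gave 18, and 28 of the 35 splits gave as many. The split by title form gave 0 genes and 8 lists. Among the 8 lists that passed, the correlation estimated among the genes of a list reached 0.77, for the interferon list, against the preset of 0.01.

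The fatty acid, glucose and contractile lists lay higher in DIZE, with a median log2 fold change of 0.20 over their 109 tested genes. With each library's trend on GC content and transcript length removed the median was 0.20 ± 0.03 (SE over genes). These genes are not independent, with estimated correlations of 0.28 to 0.39 within the lists, so the SEs given here are too small. The median did not fall with the correction, which argues against that trend as the whole cause. Without vehicle 1, which had low levels of all 3 lists, the median was 0.14 ± 0.03, against a bound of 0.10 for a loss of most of the shift. A part of the shift may come from that library, and the treatment remains open as an explanation.

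Arntl and Npas2 were higher and Per3, Nr1d2 and Tef lower in DIZE, Tef having been chosen after its values were seen (log2 -0.32 ± 0.11). With the GC and length trend removed, the median of the 5 changes, taken in the direction seen, was 0.80 against 0.77 before, with a standard error of 0.39 over genes that decides nothing by itself. Gene by gene, the correction removed a median of 0.00 ± 0.06, which argues against the trend as the cause. A collection at another time of day could shift clock genes by their phase. Of 15 clock genes with a known phase, 10 moved as such a shift would, and 5 of the 10 outside the pattern did (one-sided exact binomial p = 0.623). This test decides nothing, as the pattern was picked from the same values and clock genes are not independent. Outside the pattern, Per2 moved that way (log2 -0.75) and Nr1d1 the other way (0.84), both chosen after their values were seen. Collection time and treatment cannot be told apart here, since the labels give no times. Arntl, Npas2, Dbp and Nr1d1 also differed by title form within DIZE.

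The cell cycle list was lower in DIZE (median log2 -0.42) while the matrix list went both ways and did not pass camera (-0.19). Their 62 genes together had a median of -0.26. With the GC and length trend removed the median was -0.33 ± 0.11, against a bound of -0.13, which decides nothing by itself. The correction removed -0.01 ± 0.02 gene by gene (SE over genes, which are not independent), which argues against that trend as the cause. Atrial tissue is a candidate source, as vehicle 1 and vehicle 4 had Myl7 at 279 and 108 CPM. With the level of Myl7 as a covariate the median was -0.31 ± 0.10, against a bound of -0.13, which decides nothing by itself. By list it was -0.39 ± 0.21 for cell cycle and -0.13 ± 0.10 for matrix genes. Gene by gene the covariate removed 0.05 ± 0.02 of the shift of the cell cycle genes and -0.01 ± 0.04 of that of the matrix genes. For the cell cycle genes, the small part removed gene by gene argues against atrial tissue as the whole cause. The cell cycle list still passed with the preset correlation (camera adjusted p = 3.93e-06). That pass decides nothing by itself, as the other splits of the libraries gave a median of 10 lists past the same test. Vehicle 3, with Myl7 at 0.67 CPM, had a cell cycle level of 0.46, and DIZE 4, with Myl7 at 42.1 CPM, one of -0.13. Other libraries went with Myl7. The level was -0.6 and -0.37 in DIZE 1 and 2 (Myl7 at 1.34 and 0.789 CPM), and -0.24 in DIZE 3 (15.4 CPM). In vehicle 2, 4 and 1 it was 0.12, 0.3 and 0.47 (21.8, 108 and 279 CPM). A part from atrial tissue is therefore not excluded, and the treatment remains open as an explanation.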
